A study of Mus musculus with 2 samples.

How the data were processed

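Per the labels, MC38 cells, a mouse colon adenocarcinoma line, were injected under the skin of female C57BL/6J mice, and 1 group received a ketogenic diet from day 4 while the other stayed on a normal diet. Per the labels' protocols, tumors were taken at day 14, dead cells were removed, CD45-positive cells were enriched with magnetic beads, and libraries were made with the Chromium 3 prime chemistry version 3.1 and sequenced on a HiSeq instrument. Per the series design text, 5 mice were pooled per library. There were 2 libraries, 1 per diet, which formed the 2 groups, normal diet and ketogenic diet. With 1 library per group no variation between mice or libraries can be measured, so no test between diets was made and every difference is given as a value with an interval for counting error. Barcodes carry no mark of the mouse.

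The deposited values are raw UMI counts per gene and barcode in matrices that the authors made with Cell Ranger and did not filter to cells; version 4 is named per the file headers and version 6.0.0 per the submitters' processing notes, which also name Seurat 3.2.0 and the builds GRCm38 and mm10. Each matrix lists 32285 genes, with 827272 barcodes in the normal and 813678 in the ketogenic library, of which 612282 and 616067 hold UMIs, and sums to 37575996 and 42710007 UMIs. Of the gene IDs, 99.6% were found in the GENCODE vM21 annotation of GRCm38, which gave transcript lengths. All steps that follow were computed from these counts with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numba 0.67.0 and matplotlib 3.10.9, on 1 thread with fixed seeds.

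Barcodes with at least 500 UMIs and 300 genes were kept as candidate cells, 5671 in the normal and 5944 in the ketogenic library. Those with at most 2000 UMIs (946 and 1277) were compared with the profile of barcodes of at most 100 UMIs, which hold 4.33% and 6.09% of all UMIs, by a multinomial likelihood against 10000 simulated draws. At a false discovery rate of 0.01, 94 and 83 barcodes were not set apart from that profile and were dropped, leaving 5577 and 5861 called barcodes. Barcodes with over 10% mitochondrial UMIs (61 and 70) were removed. Scrublet, run per library with an expected rate of 0.045, set automatic thresholds of 0.373 and 0.377 that marked 0 and 1 barcodes, so it did not work on these cells. It was replaced by a filter on co-detected lineages, chosen after the cells had been seen. A barcode was mixed where at least 2 of the modules T or NK (500 CPM), myeloid (1500 CPM), B (400 CPM), tumor or stromal (800 CPM) and MHC class II in T or NK cells (1500 CPM) were present, each with at least 3 UMIs from at least 2 genes.

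This filter had 3 versions. The first used 4 lineage modules and marked 1023 and 1008 barcodes, the second added MHC class II and marked 1085 and 1101, and the third added a rule for neutrophils (3000 CPM of neutrophil genes with 1000 CPM of macrophage genes) and marked 1180 and 1204. The third was made after differences between the diets within classes had been seen and was for a time the filter of record. The second was then restored because it was the last one set before those differences were examined, when the results of both had been seen. Under the third version neutrophil-like cells numbered 154 and 92, cDC2-like cells had 17 genes 2-fold higher and 85 lower instead of 13 and 35, and the type I interferon median of NK cell-like cells was −0.15 (percentile 0.05) instead of −0.084 (percentile 3.88). Kept cells numbered 4431 and 4690, with 21668485 and 23060937 UMIs, medians of 3721 and 3419 UMIs and 1503 and 1349 genes per cell, and a median mitochondrial share of 1.94% and 1.38%. Mixed barcodes were 19.7% (18.6 to 20.7) and 19.0% (18.0 to 20.0) of the 5516 and 5791 barcodes that passed the mitochondrial limit, with medians of 10346 and 11568 UMIs.

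Counts of both libraries were scaled to 10000 per cell, log-transformed and clustered together without correction between libraries, with 2000 variable genes, 30 principal components, 15 neighbors and the Leiden algorithm at resolution 1. Clusters were named from 21 marker lists fixed before the data were examined, and are called "-like" for that reason. A name required at least 3 markers at 2-fold over the other cells, with 20 CPM added, a median log2 fold of at least 0.7, at least 2 markers among the top 30 genes by fold, and no lead of another class among the top 10. The rule as first written asked for at least 3 markers among the top 30 and for more markers of the class than of any other among the top 10, where a tie with at least 1 is now allowed, and had no minimum at 2-fold. It was replaced after 2 clusters had failed it, an interferon-led monocyte cluster by a tie and a granzyme-led NK cluster by a tie and by 2 markers among the top 30, and before differences within classes were seen. Under the first rule monocyte-like cells numbered 370 and 592 and NK cell-like cells 804 and 1468. Clusters led by cell cycle genes, or by Rhox5 at a median of 825 UMIs, stayed unnamed. Macrophage-like clusters were led by C1qa and Ccl12 and by Mmp12, Arg1, Hmox1 and the heat shock gene Hspa1b. Names rest on these clusters and are no sorted populations.

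Shares are cells of a class over all kept cells of a library, with Clopper-Pearson intervals and log2 ratios with intervals from the 2 binomial errors. UMIs were summed over the cells of each class with at least 100 cells in both libraries (7 classes), scaled to CPM (counts scaled to 1e6 UMIs per class sum) and compared as log2 ratios of CPM + 10, ketogenic over normal, for genes with at least 50 counts over both sums. CPM intervals are exact Poisson and CPM ratios have exact conditional binomial intervals. Genes at 2-fold are counted as a description of size. For 23 gene lists fixed before the data were examined, and for ribosomal protein and mitochondrially encoded genes, the median log2 ratio of members with at least 20 counts was set beside the medians of 10000 lists of as many genes drawn from 20 expression bins, and its percentile describes these 2 libraries only. A percentile outside 2.5 to 97.5 is called apart.

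The named genes were chosen by a rule fixed before the data were examined. Per class, among genes with at least 50 counts and at least 50 CPM in 1 library, without mitochondrial, ribosomal protein, immunoglobulin, T cell receptor variable, hemoglobin and unnamed genes and without markers of other classes, it took the 12 highest and 12 lowest log2 ratios that reach 1.5-fold in the 4 largest classes and 5 and 5 in the others. It added up to 4 members of each list with the largest absolute ratio, and Cd274, Pdcd1, Ctla4, Lag3, Gzmb, Ifng, Prf1, Arg1, Il1b, Nos2, Cxcl9, Hcar2, Cpt1a, Pdk4, Plin2 and Cd36 at 50 counts or more. Some further genes examined are not reported here. Genes that lead a cluster of the class are left out of its results, which removes Pdcd1 in CD8 T cell-like, Prf1 and Ifng in NK cell-like, Arg1 in macrophage-like and Hcar2 in neutrophil-like cells. Such a gene is given only where an alternative reversed its sign. Exceptions are the level of Cxcl2 in neutrophil-like cells, set beside macrophage-like cells, and the hemoglobin UMIs of NK cell-like cells. For each named gene the share of its counts in a single cell was computed, and genes resting on 1 cell are given with that share.

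The depth of the class sums ran from 441003 UMIs (other T cell-like, normal) to 6777821 (NK cell-like, ketogenic). Checks on simulated data with the real profiles used 2 depths. At 3e6 UMIs per library, 200 of 200 genes changed 3-fold reached 2-fold and 0 of 7994 unchanged genes did. At 5e5 UMIs these numbers were 184 of 200 and 3 of 2694. A list shifted by −0.4 gave medians of −0.363 and −0.351, both at percentile 0, and of 40 unshifted lists 1 and 3 lay outside the central 95%. The ambient test called 1 of 300 droplets drawn from the ambient profile. It called 189 of 300 deep barcodes thinned into the tested range, after a first simulation had been replaced, so some shallow cells may be lost. The deep barcodes included mixed ones, so this share need not hold for shallow cells of 1 lineage.

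Alternatives fixed before the data were examined were a minimum of 1000 UMIs and 500 genes without the ambient test or of 250 UMIs and 150 genes, a mitochondrial limit of 20%, doublets kept, Leiden resolutions of 0.5 and 2, genes centred within each library before the principal components, immune cells without neutrophils as denominator, cells thinned to 1000 UMIs, CPM without mitochondrial and ribosomal protein genes, the median of genes with at least 200 counts set to 0, the ambient profile subtracted, equal cluster weights, a pseudocount of 1 CPM, gene minimums of 200 and 1 counts, and list members of at least 100 counts. Added after the data had been seen were the other filter versions, removal of the 10% of barcodes with the highest Scrublet scores, the first naming rule, clustering without the genes of both interferon lists, random lists matched on transcript length as well, and the 20% limit with Scrublet's own thresholds. In that last run the normal library's threshold dropped to 0.0573 and marked 1741 barcodes, so all other alternatives keep the thresholds given above. Barcodes with C1q genes, for 1 of these tests, were those with at least 3 C1qa, C1qb and C1qc UMIs from at least 2 of these genes and at least 500 CPM. The predictions for the tests of the closing section were written before these tests were first run, under the third filter version, except those named there, and the values given come from the second version, after values of the third had been seen. The prediction on ambient RNA covered every class where the interferon list lay apart. Under the third version NK cell-like cells were one of these and did not meet it, while under the second they are not apart.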

Results

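Cells from subcutaneous MC38 colon adenocarcinoma tumors, enriched for the leukocyte marker CD45, held fewer macrophage-like and more natural killer (NK) cell-like cells in the ketogenic than in the normal diet library. Macrophage-like cells, phagocytes of the tumor, made up 30.3% (29.0 to 31.7, 1344 cells) of the normal and 12.1% (11.2 to 13.1, 569 cells) of the ketogenic library, a log2 ratio of −1.32 (−1.45 to −1.19). NK cell-like cells, cytotoxic innate lymphocytes, made up 19.995% (18.8 to 21.2; 886 cells) of the normal and 33.8% (32.4 to 35.1; 1584 cells) of the ketogenic library, a log2 ratio of 0.76 (0.65 to 0.86). Monocyte-like cells, the blood-derived precursors of macrophages, made up 20.2% and 21.8%. They join 2 clusters that went opposite ways. A cluster led by Cxcl10, Vcan and Gbp2 held 523 and 431 cells, and a cluster led by Hp, Chil3 and Fn1 held 370 and 592 cells. Monocyte-like and macrophage-like cells combined made up 50.5% and 33.9% (log2 ratio −0.57 (−0.64 to −0.50)). Each diet had 1 library made from 5 pooled female mice at tumor day 14. Differences are given by size and were not tested. The 95% intervals (Clopper-Pearson for shares, exact Poisson or conditional for counts) cover counting error only. Shares refer to CD45-enriched barcodes with at least 500 UMIs, 300 genes and 1 lineage, and the median kept barcode held 3721 UMIs in the normal and 3419 in the ketogenic library. Shares add up to a fixed whole, so a lower macrophage share by itself raises the shares of the other classes. Shares without macrophage-like cells were not computed.

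Among T cells, CD8 T cell-like cells, which kill tumor cells, made up 5.42% and 5.78% of the normal and ketogenic libraries. Regulatory T cell-like cells, which restrain other T cells, made up 1.58% and 1.64%, and the remaining T cell-like cells 3.14% and 4.78% (log2 ratio 0.61 (0.31 to 0.91)). Type 2 conventional dendritic cell (cDC2)-like cells, which present antigen to CD4 T cells, were lower in the ketogenic library at 4.47% and 2.56% (log2 ratio −0.80 (−1.13 to −0.48)). CCR7-positive dendritic cell-like cells made up 1.49% and 1.32% and plasmacytoid dendritic cell-like cells 0.632% and 0.746%. Neutrophil-like cells, short-lived granulocytes, made up 5.87% and 4.14% (log2 ratio −0.50 (−0.77 to −0.24)), and mast cell or basophil-like cells 0.519% and 1.11% (log2 ratio 1.09 (0.39 to 1.80)). B cell-like cells made up 0.248% and 0.299% and fibroblast-like cells 1.20% and 1.81%. Xist, an RNA of female cells, was low in the latter (8.74 and 7.39 CPM), which argues against host fibroblasts as most of them. Clusters without a name, led by the cell cycle genes Stmn1, Top2a and Mki67 or by Rhox5 and Cald1, held 4.92% and 6.52%. The neutrophil log2 ratio was −0.82 with a further filter on mixed neutrophil barcodes and 0.021 when cells were thinned to 1000 UMIs before clustering. Neutrophil-like barcodes had a median depth of 1273 UMIs in the normal library, the lowest there of the classes compared below, and of 2621 in the ketogenic library.

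**Figure D1:**
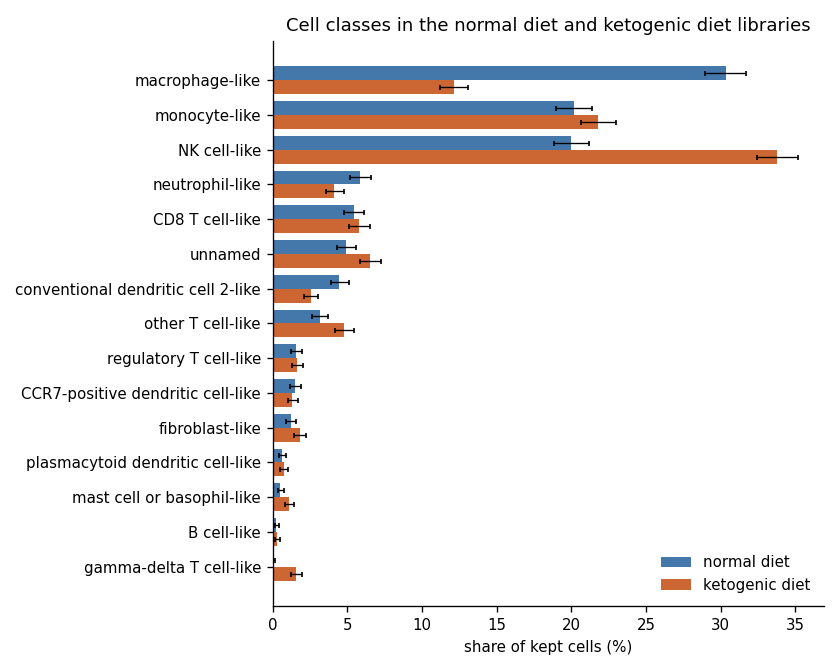
Share of kept cells in each class in percent (bars from 0, 1 bar for each of the normal and ketogenic diet libraries), with 95% Clopper-Pearson intervals that cover counting error only. Macrophage-like cells stand at 30.3% in the normal and 12.1% in the ketogenic library, and NK cell-like cells at 19.995% and 33.8%.

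A population of gamma-delta T cell-like cells with Il17a, the cytokine that draws neutrophils to inflamed tissue, was found almost wholly in the ketogenic library. It made up 0.0451% (0.00547 to 0.163; 2 cells) of the normal and 1.58% (1.24 to 1.98; 74 cells) of the ketogenic library, and a cluster held mostly by 1 library may be a property of that library. Over all called barcodes, mixed ones included, Il17a had 5 UMIs in the normal and 755 in the ketogenic library, or 0.141 (0.0459 to 0.330) and 19.1 (17.7 to 20.5) CPM, a ratio of 135 (57.6 to 417). Trdc, the constant chain of the delta receptor, had 23.8 and 47.3 CPM. Tcrg-C1, a constant chain of the gamma receptor, had 4.21 and 12.3 CPM, and Cd163l1, a scavenger receptor of Il17a-making gamma-delta cells, 0.565 and 7.48 CPM. These genes were chosen after their values were seen. Trdc was at 57.5 and 55.0 CPM in NK cell-like cells and at 209 and 132 CPM in the other T cell-like cells, so the gene marks more than 1 class.

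**Figure D2:**
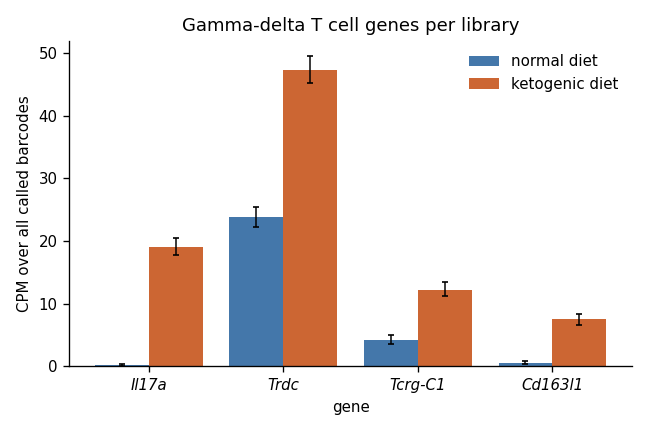
CPM values of Il17a, Trdc, Tcrg-C1 and Cd163l1 over all called barcodes of the normal and ketogenic diet libraries, with 95% Poisson intervals that cover counting error only. Il17a stands at 0.141 CPM in the normal and 19.1 CPM in the ketogenic library.

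Type I interferon-stimulated genes, the antiviral response set, were lower in the ketogenic library within monocyte-like, macrophage-like, CD8 T cell-like, other T cell-like and cDC2-like cells. The median log2 ratio, ketogenic over normal, was −0.38 in monocyte-like cells (44 members measured, 11 at least 1.5-fold lower, 0 higher) and −0.38 in macrophage-like cells (44 measured, 14 lower). It was −0.38 in CD8 T cell-like cells (41 measured, 12 lower), −0.33 in the other T cell-like cells (42 measured, 7 lower) and −0.45 in cDC2-like cells (44 measured, 16 lower). No member was 1.5-fold higher in any of these 5 classes. Each median lay at percentile 0 among 10000 lists of as many genes drawn at the same expression. Percentiles describe these libraries and stand for no test. Rsad2, the radical enzyme viperin, was at 2230.2 (2179 to 2282) and 1134 (1099.7 to 1170.0) CPM in monocyte-like cells, 1318 and 644 CPM in macrophage-like cells and 229 and 85.9 CPM in CD8 T cell-like cells. Oas3, a sensor of double-stranded RNA, was at 333 and 179.6 CPM, 244 and 114 CPM and 99.8 and 48.3 CPM in the same classes. In NK cell-like cells the median was −0.084 (percentile 3.88) and in neutrophil-like cells −0.11 (percentile 5.64), inside the central 95% of lists. Of the alternatives, 7 took the NK and 8 the neutrophil median below that range.

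Interferon-gamma-induced genes were lower in the same classes and, unlike type I genes, also stood apart in neutrophil-like cells. Medians were −0.43 in monocyte-like (6 of 29 members 1.5-fold lower) and −0.36 in macrophage-like (5 of 29) cells. They were −0.37 in CD8 T cell-like (4 of 21), −0.31 in other T cell-like (3 of 21), −0.48 in cDC2-like (7 of 25) and −0.36 in neutrophil-like cells (8 of 27). These 6 medians lay at percentiles of 0.03 or less, while NK cell-like cells had −0.081 (percentile 18.9). Iigp1, an interferon-inducible GTPase, was at 166 and 102 CPM in macrophage-like cells, and Gbp7, a guanylate-binding protein, at 229.5 and 141 CPM. Neutrophil-like cells also differed in macrophage RNA, with C1qa at 813 and 83.1 CPM. At a mitochondrial limit of 20% with Scrublet's own thresholds their log2 ratios of Iigp1 and Irf8 turned from −1.04 to 0.64 and from −0.68 to 0.46. That of Gbp4 went from −0.96 to −0.090. Whether neutrophils themselves had lower interferon-gamma-induced genes was not tested. The monocyte class joins a cluster led by Cxcl10, Gbp2 and Ifit2, themselves interferon-induced, with a cluster led by Hp, Chil3 and Fn1. The normal library held more of its monocyte-like cells in the first. With each cluster given the same weight in both libraries the type I interferon median of monocyte-like cells was −0.16 (percentile 0.01). In the Hp, Chil3 and Fn1 cluster alone, which the naming rule as first written would keep, it was −0.085 (percentile 8.35). Beside these lists, mitochondrially encoded genes had medians of −0.56, −0.64, −0.33, −0.59 and −0.46 in monocyte-like, macrophage-like, CD8 T cell-like, other T cell-like and cDC2-like cells. Ribosomal protein genes had medians of 0.18, 0.19, 0.14, 0.098 and 0.22 in the same order. Of 4 bins of genes by transcript length, the longest had a median log2 ratio of −0.17 in monocyte-like, −0.18 in macrophage-like, −0.13 in CD8 T cell-like, −0.13 in other T cell-like and −0.24 in cDC2-like cells. The shortest bin had 0.072, 0.026, 0.077, 0.068 and 0.062.

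**Figure D3:**
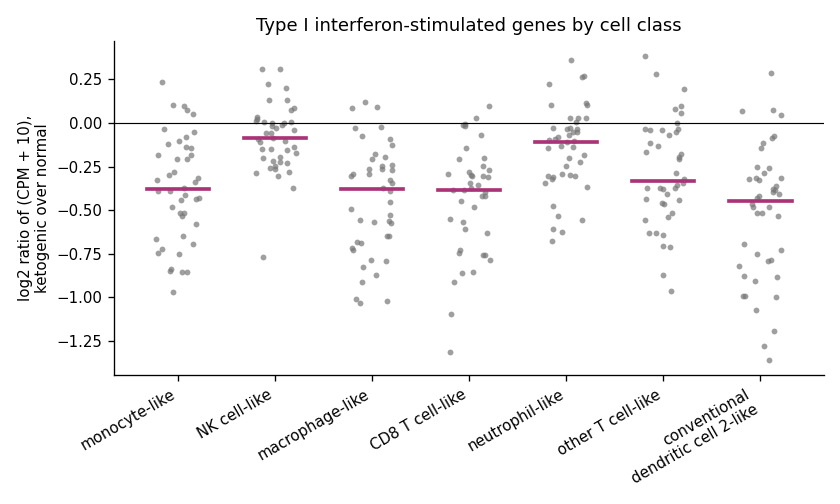
Log2 ratio of CPM + 10, ketogenic over normal library, of each measured type I interferon-stimulated gene (points) and the list median (bars) in 7 cell classes. The median lies between −0.45 and −0.33 in 5 classes, at −0.084 in NK cell-like cells and at −0.11 in neutrophil-like cells.

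Macrophage-like cells of the ketogenic library had higher RNA of chemokine genes, among them Cxcl2, and lower RNA of interferon-stimulated genes. Cxcl2, a chemokine that recruits neutrophils, was at 340.1 (326 to 355) and 1277 (1231 to 1324) CPM, a ratio of 3.75 (3.55 to 3.97), and its neighbor Cxcl3 at 25.7 and 85.5 CPM. Plaur, the receptor of urokinase, was at 142 (133 to 152) and 312 (289.6 to 336) CPM, and Cd14, the coreceptor for lipopolysaccharide, at 285 and 532 CPM. Spp1, the matrix protein osteopontin, was at 849 and 1434 CPM, Il1b, the inflammasome-processed cytokine, at 994 and 1459 CPM, and Id1, an inhibitor of basic helix-loop-helix factors, at 21.6 and 72.5 CPM. The chemokine list had a median of 0.27 (percentile 100), with 5 of 20 members 1.5-fold higher and 2 lower. The inflammatory cytokine list had 0.11 (percentile 99.9) with 3 of 26 higher, and the neutrophil recruitment and suppressor cell list 0.19 (percentile 100) with 1 of 20 higher. Among genes lower in the ketogenic library, Ccl8, a monocyte-attracting chemokine, was at 259 (246 to 272) and 98.1 (85.7 to 112) CPM and Ccnd2, a cyclin of the G1 phase, at 295 and 135 CPM. Herc6, an interferon-induced ligase, was at 179.9 and 90.7 CPM, and the noncoding RNAs Neat1 and Xist at 324 and 157 CPM and 487 and 226 CPM. These RNAs were also lower over all called barcodes, Neat1 at 354 and 162 CPM and Xist at 619 and 445 CPM. In the ambient profile they were at 318 and 123 CPM and 424 and 228 CPM, so their difference is not particular to macrophage-like cells. Cd274, which encodes PD-L1, was at 152 and 153 CPM and Nos2, the inducible nitric oxide synthase, at 37.0 and 30.4 CPM. Of 8301 genes measured in macrophage-like cells, 5 were 2-fold higher and 11 were 2-fold lower in the ketogenic library. More were higher than lower with the median of genes with at least 200 counts set to 0. More were lower at a pseudocount of 1 CPM.

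Neutrophil marker genes summed to 1079.5 and 1164 CPM and NK cell markers to 3196 and 3747 CPM in macrophage-like cells of the normal and ketogenic libraries. Cxcl2 stood at 6010 and 6583 CPM in the neutrophil-like cells of the 2 libraries, the class with the highest level. Cell cycle genes had a median of 0.29 (percentile 100), with 4 of 29 members 1.5-fold higher. Birc5, an inhibitor of apoptosis made in mitosis, was at 13.8 and 36.9 CPM, and Pclaf, a binding partner of the replication clamp, at 17.5 and 37.8 CPM. Mitochondrially encoded genes had a median of −0.64 (percentile 0), with 8 of 13 at least 1.5-fold lower, and ribosomal protein genes 0.19 (percentile 100). A single cell held 99.2% of the ketogenic counts of Retnla, a gene of alternatively activated macrophages, so its 116 and 212 CPM are not read as a difference.

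Monocyte-like cells of the ketogenic library shared several of these genes. Cxcl2 was at 155 (142 to 169) and 469.7 (447 to 493) CPM, a ratio of 3.04 (2.75 to 3.36), Plaur at 259.5 and 509 CPM and Cd14 at 389 and 699 CPM, while Il1b was at 1509 and 1829 CPM. Hilpda, an inhibitor of lipid droplet lipolysis, was at 54.2 and 126 CPM, Pla2g7, a secreted phospholipase, at 247 and 486 CPM, and Id3, an inhibitor of basic helix-loop-helix factors, at 73.7 and 149 CPM. Lower in the ketogenic library were Tgm2, a transglutaminase, at 507 and 266 CPM and Nfkbiz, a nuclear regulator of NF-kB targets, at 152 and 77.1 CPM. Lower too were Ccnd2 at 125 and 55.2 CPM, Cd274 at 118 and 82.2 CPM and Neat1 at 939 and 393 CPM. The MHC class II list had a median of −0.15 (percentile 10.5), the inflammatory cytokine list 0.073 (percentile 95.3) and the chemokine list 0.11 (percentile 93.5). Of 7204 genes measured, 4 were 2-fold higher and 5 were 2-fold lower. With the median of genes with at least 200 counts set to 0 more were higher, and at a pseudocount of 1 CPM more were lower. Because the libraries fill the interferon-led and the Hp, Chil3 and Fn1 clusters differently, values of the class also carry that makeup: in the latter cluster alone the Cxcl2 log2 ratio was 0.95 instead of 1.54. Beside them, mitochondrially encoded genes had a median of −0.56 (percentile 0) with ribosomal protein genes at 0.18 (percentile 100).

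**Figure D4:**
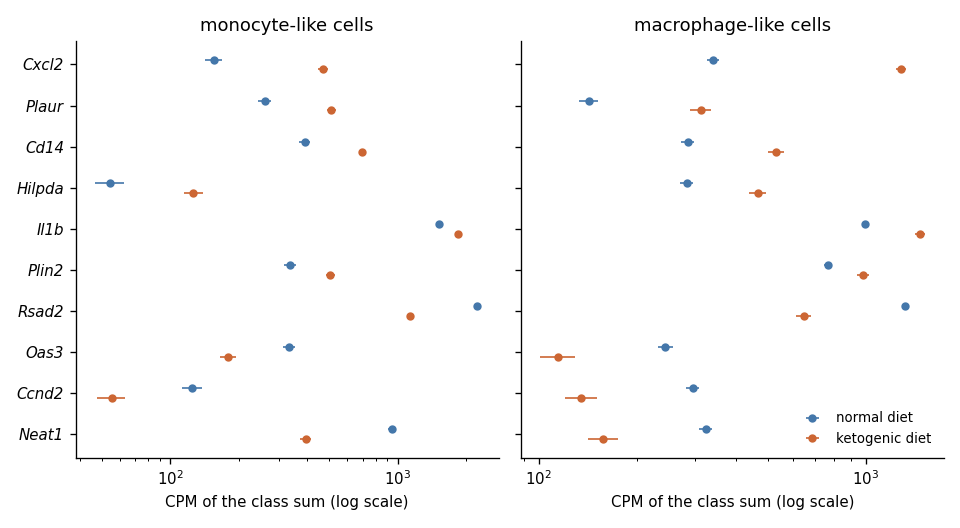
CPM values of 10 genes (log axis) in monocyte-like and macrophage-like cells of the normal and ketogenic diet libraries, with 95% Poisson intervals that cover counting error only. Cxcl2 stands at 155 and 470 CPM in monocyte-like and at 340 and 1277 CPM in macrophage-like cells, and Rsad2 at 2230 and 1134 CPM and at 1318 and 644 CPM.

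NK cell-like cells of the ketogenic library had lower list medians of cytotoxic, cell cycle and cholesterol and fatty acid synthesis genes, with few members at 1.5-fold. Gzmb, a granzyme that triggers apoptosis of target cells, was at 4220.3 (4160.1 to 4281) and 3655 (3609.6 to 3701) CPM, and the cytotoxic list had a median of −0.065 (percentile 0.97), with 1 of 31 members 1.5-fold higher and 0 lower. Among genes higher in the ketogenic library, Klf2, a factor that controls lymphocyte trafficking, was at 114 (105 to 125) and 216 (205 to 227) CPM, and Nfkbia, the inhibitor of NF-kB, at 244 and 422 CPM. Ifrd1, a transcriptional coregulator on neither interferon list, was at 44.0 and 101 CPM, and Nr4a1, a receptor induced by activation, at 78.2 and 130.3 CPM. The immediate early and heat shock list had a median of 0.018 (percentile 65.2). Lower were Oas3 at 73.0 and 38.8 CPM and S100a4, a calcium-binding protein of motile cells, at 747 and 485 CPM. Itga1, a collagen-binding integrin of tissue-resident cells, was at 142 and 88.7 CPM, and Nabp1, a single-stranded DNA-binding protein, at 153 and 81.7 CPM. The inhibitory receptor gene Lag3 was at 69.9 and 70.2 CPM and Ctla4 at 44.4 and 50.2 CPM. Cell cycle genes had a median of −0.20 (percentile 0) with 2 of 27 members 1.5-fold lower, and cholesterol and fatty acid synthesis genes −0.25 (percentile 0) with 1 of 26 lower. Of the latter, Scd2, a desaturase, was at 46.9 and 24.9 CPM and Hmgcs1, a synthase of the sterol pathway, at 34.3 and 19.8 CPM.

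The NK class joins clusters led by Hbb-bs, Gzmc and Xcl1, by Gzma, Klrb1c and Ccl5, and by Gzmg and Gzmd. A cluster led by Stmn1, Top2a and Mki67 with NK cell markers as its best, 141 and 231 cells, stayed unnamed and lies outside the class. The Gzma cluster held 350 of 886 NK cell-like cells in the normal and 788 of 1584 in the ketogenic library, and the Xcl1 cluster 454 and 680. Of the hemoglobin UMIs of the class in the normal library, 90.8% lay in 1 barcode. Of 8604 genes measured, 2 were 2-fold higher and 10 were 2-fold lower. Macrophage markers summed to 3300 and 2690.4 CPM and monocyte markers to 3224 and 2768 CPM in NK cell-like cells. MHC class II genes, typical of antigen-presenting cells, had a median of −0.35 (percentile 0), which became 0.049 (percentile 91.5) with the ambient profile subtracted. The chemokine list, at −0.25 (percentile 0.01), became 0.50 with the ambient profile subtracted and 0.49 with members of at least 100 counts only. Mitochondrially encoded genes had a median of −0.51 (percentile 0) and ribosomal protein genes 0.051 (percentile 37.1).

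CD8 T cell-like cells of the ketogenic library had lower RNA of Gzmb and of glycolysis genes beside the lower interferon genes. Gzmb was at 3228 (3125 to 3334) and 2181 (2106 to 2257) CPM, a ratio of 0.676 (0.644 to 0.708), Prf1, the pore-forming perforin, at 937 and 730.5 CPM, and Lag3 at 401 and 286 CPM. Cd160, a receptor of activated killer cells, was at 40.8 (29.96 to 54.2) and 88.6 (74.2 to 105) CPM. Zfp36l2, an RNA-binding protein that promotes mRNA decay, was at 168 and 314 CPM, and Gpr183, a receptor for oxysterols, at 73.7 and 136 CPM. Il10ra, the interleukin 10 receptor, was at 111 and 47.7 CPM and Stat2, a transducer of type I interferon signals, at 52.9 and 19.5 CPM. Ctla4 was at 192 and 153 CPM, and Neat1 at 135 and 61.1 CPM. The cytotoxic list had a median of −0.089 (percentile 2.83) with 2 of 31 members 1.5-fold higher and 1 lower. The checkpoint and costimulatory list had −0.13 (percentile 4.95) with 2 of 27 higher and 1 lower. Glycolysis genes had a median of −0.29 (percentile 0.09), with 2 of 18 lower. The glucose transporter Slc2a1 was at 67.7 and 36.3 CPM and Slc2a3 at 87.6 and 45.0 CPM. Cell cycle genes had a median of 0.21 (percentile 99.8), with Cdk1, a kinase of mitotic entry, at 10.4 and 25.5 CPM. An unnamed cycling cluster with CD8 T cell markers as its best, 30 and 31 cells, lies outside the class. Of 5253 genes measured, 3 were 2-fold higher and 14 were 2-fold lower. Monocyte markers summed to 5547 and 4111 CPM in these cells, and mitochondrially encoded genes had a median of −0.33 (percentile 0.035). A single cell held 28.4% of the ketogenic counts of Ifng, the type II interferon, at 600.3 and 461 CPM, and 70.4% of the normal counts of Gzmg, a granzyme.

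The other T cell-like cells, with Cd3d, Klra1 and Tcf7 among their leading genes, had Gzmb at 1812 (1688 to 1942) and 1242 (1159 to 1329) CPM and Oasl2, a member of the oligoadenylate synthetase family, at 179 and 93.5 CPM, both lower in the ketogenic library. Nfil3, a factor needed for innate lymphocyte development, was at 31.7 and 81.6 CPM and Hadha, an enzyme of fatty acid oxidation, at 43.1 and 78.6 CPM. The class had 139 and 224 cells, and of 2869 measured genes 3 were 2-fold higher and 13 were 2-fold lower. Monocyte markers summed to 5707 and 4583 CPM, macrophage markers to 1265 and 975 CPM and NK cell markers to 6968 and 7997 CPM in these cells, and mitochondrially encoded genes had a median of −0.59 (percentile 0).

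In cDC2-like cells of the ketogenic library, genes of the interferon response were lower and genes of inflammatory cytokines were higher. Ifit1, an interferon-induced binder of foreign RNA, was at 548 (499.7 to 599) and 219.6 (182 to 263) CPM, Cxcl9, a chemokine that attracts T cells, at 378 and 214 CPM, and Cd274 at 108 and 63.3 CPM. Tnfsf9, a costimulatory ligand, was at 60.9 (45.6 to 79.6) and 189.8 (155 to 230.4) CPM and Il1b at 982 and 1541 CPM. The inflammatory cytokine list had a median of 0.49 (percentile 100), with 8 of 17 members 1.5-fold higher and 2 lower. Hhex, a homeobox factor, was at 106 and 33.5 CPM. The MHC class II list, whose members lead this cluster, had a median of −0.28 (percentile 0.32). The checkpoint and costimulatory list had −0.38 (percentile 0.15), though 4 of 20 members were 1.5-fold higher and 3 lower. Of 3482 genes measured, 13 were 2-fold higher and 35 were 2-fold lower. Type 1 conventional dendritic cell markers, for which no cluster was named, summed to 9485 and 13141 CPM in these cells, macrophage markers to 8608 and 7659 CPM and NK cell markers to 2935 and 3398 CPM. The cytotoxic list had a median of 0.46 (percentile 100) that turned to −0.016 with mixed barcodes removed by 4 lineage modules only, and mitochondrially encoded genes stood at −0.46 (percentile 0.03).

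Neutrophil-like cells had nearly the same level of Il1b in both libraries, 5753 (5591 to 5918) and 5614 (5430.1 to 5803) CPM, and of Plin2, a coat protein of lipid droplets, at 596 and 596 CPM. Hilpda was at 482 and 869.6 CPM, Cd274 at 405 and 264 CPM, Rsad2 at 4877 and 3196 CPM and Ccl3, a macrophage inflammatory chemokine, at 1782 and 854 CPM. Of 3652 genes measured, 26 were 2-fold higher and 78 were 2-fold lower. RNA of other cells also differed in this class: macrophage markers summed to 24080 and 18313 CPM, T cell markers to 379.6 and 779 CPM and NK cell markers to 5478 and 7555 CPM. C1qa, a complement gene of macrophages, was at 813 and 83.1 CPM and Trbc2, a T cell receptor constant chain, at 57.8 and 181 CPM, both chosen after their values were seen. The MHC class II list had a median of −1.16 (percentile 0) and the alternatively activated and suppressive macrophage list −0.49 (percentile 0). The LXR target and cholesterol efflux list had −0.54 (percentile 0.03) and the cytotoxic list 0.39 (percentile 100). Ribosomal protein genes stood at 0.39 (percentile 100) and mitochondrially encoded genes at −0.18 (percentile 8.26). With a mitochondrial limit of 20% and doublets marked at Scrublet's own threshold in that run, the Il1b log2 ratio was −0.99, that of Rsad2 −1.29, that of Ccl3 −1.98 and that of Hilpda 0.16. There the MHC class II median turned to 1.15, and that of the alternatively activated and suppressive macrophage list turned positive as well.

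Nuclear-encoded genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, were higher in the ketogenic library in all 7 classes. The median over 76 members was 0.26 in monocyte-like, 0.16 in NK cell-like and 0.18 in macrophage-like cells. It was 0.20 in CD8 T cell-like, 0.25 in neutrophil-like, 0.15 in other T cell-like and 0.18 in cDC2-like cells, each at percentile 99.9 or 100. Among lists matched on transcript length as well, whose own medians ran from 0.033 to 0.10, the percentiles were between 98.6 and 100. Few members reached 1.5-fold, from 0 in monocyte-like to 4 higher in neutrophil-like cells and 3 higher and 2 lower in cDC2-like cells. Ndufa3, a subunit of complex I, was at 171 and 256 CPM in monocyte-like, 145 and 244 CPM in macrophage-like and 142 and 218 CPM in NK cell-like cells, and Atp5e, a subunit of ATP synthase, at 719.7 and 1001 CPM in NK cell-like cells. Mitochondrially encoded genes, which encode subunits of the same complexes, had medians from −0.64 in macrophage-like to −0.18 in neutrophil-like cells, inside the central 95% of lists only in the latter. Ribosomal protein genes were at medians between 0.051 and 0.39.

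Fatty acid uptake and oxidation genes, the set most tied to a diet of fat, had small positive medians: 0.096 (percentile 100) in monocyte-like, 0.053 (percentile 99.9) in NK cell-like, 0.055 (percentile 91.6) in CD8 T cell-like, 0.16 (percentile 98.7) in other T cell-like and 0.20 (percentile 100) in cDC2-like cells. Plin2 was at 335 and 505 CPM in monocyte-like and 766 and 979 CPM in macrophage-like cells, and Hilpda at 283 and 467 CPM in macrophage-like cells. Etfb, an electron carrier of fatty acid oxidation, was at 97.2 and 169 CPM in monocyte-like and 150.1 and 232 CPM in CD8 T cell-like cells. Cpt1a, which brings fatty acids into mitochondria, was at 32.1 and 29.1 CPM in macrophage-like cells. The medians of macrophage-like cells (0.010 (percentile 99)) and neutrophil-like cells (0.10 (percentile 99.7)) changed sign under 7 and 2 alternatives. Ketone body genes showed no shared direction, with medians from −0.18 in macrophage-like to 0.15 in neutrophil-like cells and percentiles from 20.1 to 93.9 over 6 classes. Oxct1, which turns ketone bodies into acetyl-CoA units, was lower in monocyte-like cells of the ketogenic library at 39.9 (33.4 to 47.3) and 17.2 (13.1 to 22.1) CPM, and at 40.5 and 28.2 CPM in macrophage-like cells. Hcar2, the receptor for beta-hydroxybutyrate, was at 26.8 and 22.6 CPM in macrophage-like and 18.6 and 18.9 CPM in monocyte-like cells. The kinase gene Pdk4 stayed under 50 counts in all classes.

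Glycolysis genes, lowest in CD8 T cell-like cells, had medians of −0.16 (percentile 4.4) in monocyte-like, −0.11 (percentile 3.31) in NK cell-like, −0.26 (percentile 1.26) in cDC2-like, −0.22 (percentile 3.85) in neutrophil-like and 0.027 (percentile 78.6) in macrophage-like cells. Hypoxia-induced genes stood at 0.097 (percentile 99.3) in macrophage-like cells, a sign that 3 alternatives turned. In neutrophil-like cells they stood at −0.32 (percentile 0.58), which turned positive at a mitochondrial limit of 20% with Scrublet's own thresholds. Cholesterol and fatty acid synthesis genes stood at −0.20 (percentile 4.23) in monocyte-like and 0.18 (percentile 99.6) in CD8 T cell-like cells, where Idi1, an isomerase of the sterol pathway, was at 10.4 and 27.5 CPM and the median turned to −0.051 with the highest 10% of Scrublet scores removed instead. LXR target and cholesterol efflux genes stood at −0.22 (percentile 0.39) in NK cell-like cells. Integrated stress and AMPK-related genes stood at −0.21 (percentile 2.4) in macrophage-like and −0.15 (percentile 2.5) in NK cell-like cells. Alternatively activated and suppressive macrophage genes stood at −0.078 (percentile 21) in macrophage-like cells, though 5 of 30 members were 1.5-fold higher and 2 lower. In monocyte-like cells they stood at −0.17 (percentile 4.95), with 1 of 22 members higher and 3 lower. In the same order, NLRP3 inflammasome genes stood at −0.086 (percentile 38) and −0.17 (percentile 9.32), and MHC class I presentation genes at −0.033 (percentile 21.8) and −0.13 (percentile 5.44). Naive and memory T cell genes stood at 0.080 (percentile 83.2) in CD8 T cell-like and −0.079 (percentile 19.6) in other T cell-like cells, and regulatory T cell genes at −0.21 (percentile 2.73) and −0.052 (percentile 25.2). Immediate early and heat shock genes stood at −0.20 (percentile 0.74) in neutrophil-like cells, with 4 of 28 members 1.5-fold lower and 2 higher. They stood at −0.051 (percentile 17.7) in CD8 T cell-like, −0.073 (percentile 7.2) in other T cell-like, −0.012 (percentile 36.8) in monocyte-like, 0.061 (percentile 79.5) in macrophage-like and 0.049 (percentile 55.7) in cDC2-like cells. Mitochondrially encoded genes had medians between −0.64 and −0.33 in the classes other than neutrophil-like cells, where it was −0.18 (percentile 8.26).

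**Figure D5:**
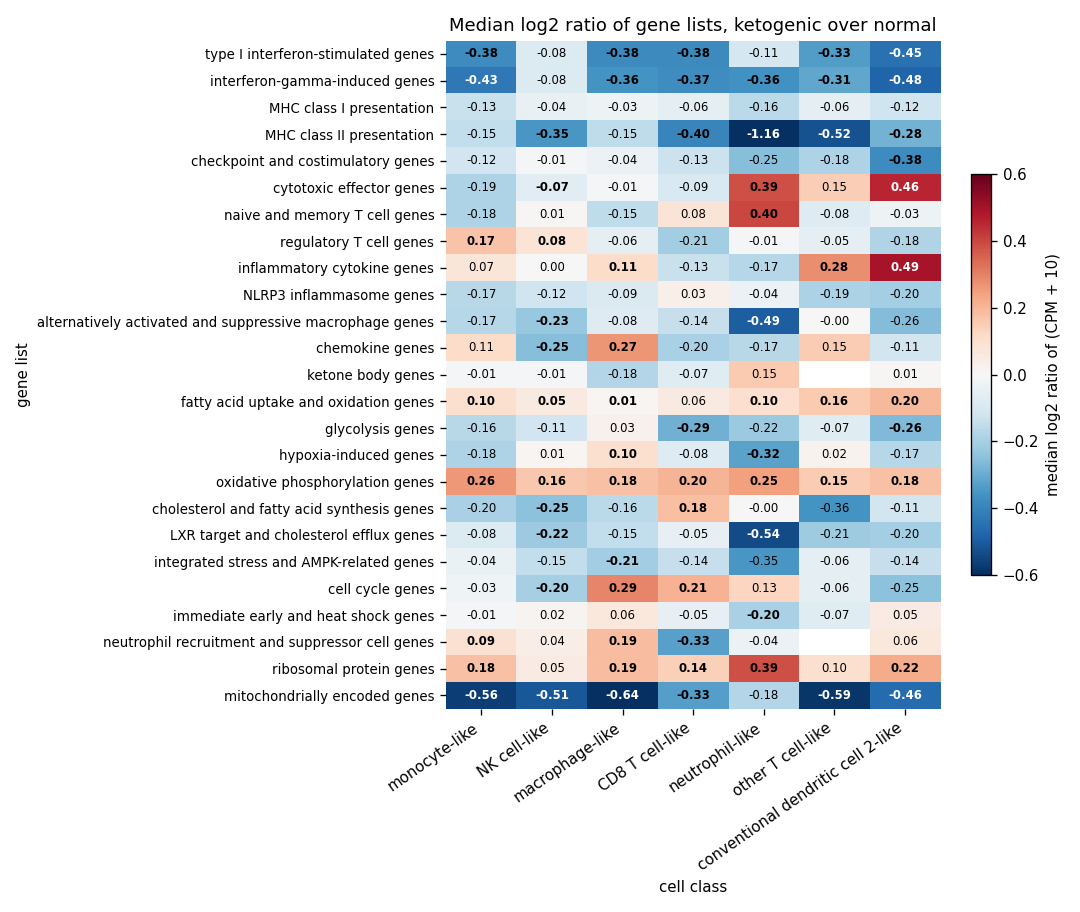
Median log2 ratio of CPM + 10, ketogenic over normal library, of each gene list (rows) in each of 7 cell classes (columns), with values in bold where the percentile among 10000 lists of the same size and expression lies outside the central 95%. Type I interferon-stimulated and mitochondrially encoded genes are negative and oxidative phosphorylation genes positive in all 7 classes.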

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

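The tests of the diet against pool, library, dissociation or enrichment, of the removal of mixed barcodes and of 1 mouse of the pool were chosen after the results were seen. Mixed barcodes enter none of the comparisons within classes. The marker list for gamma-delta T or innate lymphoid cells was examined in them. The genes named next had a lower counting bound in the ketogenic library above the upper counting bound in the normal library. Not all of these genes are particular to gamma-delta T cells. In mixed barcodes of the ketogenic library Il17a was at 25.5 CPM against 0 in the normal library, Trdc at 49.9 against 25.5, Tcrg-C1 at 15.4 against 5.90, Tcrg-C2 at 23.2 against 17.6, Trdv4 at 5.02 against 1.60 and Trgv2 at 8.35 against 3.43. Cd163l1 was at 9.14 against 1.02 CPM, Blk at 3.75 against 0.510, Rora at 32.1 against 25.3 and Areg at 38.3 against 11.2. The markers Gata3, Il23r, Il1rl1, Il13, Il5, Kit and Ly6g5b did not meet this rule.

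Type I interferon-stimulated genes were lower in 5 classes of the ketogenic library. Different cluster makeup of a class would bring the median back among other lists once clusters are weighted alike, but the highest percentile was 0.01, over monocyte-like and macrophage-like cells, although the monocyte median was then −0.16 instead of −0.38 and 1 monocyte cluster is itself led by interferon-induced genes. Transcript length would do so among lists matched on length, and ambient RNA after subtraction of the ambient profile, but the highest percentile over the 5 classes was 0 in both tests, although in the monocyte cluster kept by the first naming rule alone the percentile was 8.35. Diet rather than pool or library cannot be told apart with 1 library per diet, and the lower mitochondrially encoded genes and the higher ribosomal protein genes show that the libraries differ in more than interferon. A weaker interferon response of tumor leukocytes under a ketogenic diet may be a hypothesis for separate mice.

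The ketogenic library had a lower macrophage and a higher NK cell share. The tests on the UMI minimum and on mixed barcodes bear on the macrophage share only. The NK cell share also rises where the macrophage share falls, but such a fall alone would raise all other classes by the same ratio. The log2 ratio was 0.76 (0.65 to 0.86) in NK cell-like and 0.61 (0.31 to 0.91) in other T cell-like cells. It was 0.11 (−0.0010 to 0.23) in monocyte-like, 0.093 (−0.15 to 0.34) in CD8 T cell-like and −0.80 in cDC2-like cells. This argues against the macrophage fall as the only source of the NK rise in these libraries. How much of the rise it makes up was not computed. The UMI and gene minimum for cells would bring the macrophage log2 share ratio to 0, but its upper bound was at most −1.19 under the higher and the lower minimum. The removal of mixed barcodes would bring to 0 the log2 ratio of barcodes with C1q genes when mixed ones are counted, but its upper bound was −1.05 (23.6% in the normal and 10.4% in the ketogenic library), by a rule met by 54.4% and 50.8% of macrophage-like cells. Diet rather than pool, dissociation or enrichment cannot be told apart with 1 library per diet, since digestion of tumors and CD45 beads can favor one class. A lower share of CD45-enriched barcodes does not show a smaller number of cells. A smaller macrophage pool under the ketogenic diet may be a hypothesis for cell counts in separate mice.

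Gamma-delta T cell-like cells with Il17a were nearly all in the ketogenic library. Clustering or the filters on barcodes would leave the Il17a ratio over all called barcodes near 1, but its lower bound was 57.6. This bears on Il17a RNA only, a gene that leads a cluster already seen to hold 2 and 74 cells. The called barcodes of the normal library held 843 Trdc and 149 Tcrg-C1 UMIs, of which 0 and 4 lay in the gamma-delta class. The test thus cannot show whether gamma-delta T cells without Il17a lay in other classes of the normal library. Ambient RNA would spread Il17a over cells as all UMIs. Of the Il17a UMIs of kept ketogenic cells, 87.4% (83.3 to 90.8) lay in the gamma-delta class, which holds 0.860% of their UMIs. Of the 755 over all called barcodes, 291 lay in this class and 422 in mixed barcodes. Il17a is itself a leading gene of this cluster and on its marker list. Its share there was thus partly set by the clustering, and this share alone cannot exclude ambient RNA. The interval of the share counts UMIs as independent, although those of the class come from at most 74 cells. Ambient RNA alone would hold Il17a at its ambient profile level. That level was 7.69 CPM (upper bound 11.9) in the ketogenic library, against 19.1 (17.7 to 20.5) CPM over all called barcodes. Ambient upper bounds of Trdc and Tcrg-C1 (42.98 and 8.55 CPM) also lay below their called lower bounds (45.2 and 11.2 CPM). Those of Cd163l1 overlapped (7.07 and 6.65 CPM). This argues against ambient RNA as the only source of Il17a in called ketogenic barcodes. With 1 library per diet and no mark of the mouse on the barcodes, 1 mouse of the pool with such cells cannot be told apart from the diet. An expansion of Il17a-making gamma-delta cells under the diet may be a hypothesis to be tested per mouse.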

How the results depend on the processing

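The alternatives on the filter of mixed barcodes, the Scrublet scores and thresholds, the naming rule, the interferon genes in clustering and the matching on transcript length were tests chosen after the data had been seen. No paired analysis was possible because each diet has 1 library of pooled mice. Depth and the single library limit every value: the intervals cover counting error only, class sums hold 441003 to 6777821 UMIs, and no alternative can show how mice or libraries vary. The type I interferon median stayed negative in macrophage-like cells (−0.39 to −0.24), CD8 T cell-like (−0.41 to −0.28), cDC2-like (−0.51 to −0.35), other T cell-like (−0.45 to −0.14), neutrophil-like (−0.35 to −0.062) and monocyte-like cells (−0.43 to −0.085), and in NK cell-like cells it ranged from −0.19 to 0.013. The log2 share ratio ranged from −1.48 to −1.17 for macrophage-like, from 0.53 to 0.79 for NK cell-like and from 4.80 to 5.22 for gamma-delta T cell-like cells. Of the share ratios under alternatives, 218 lay within the counting interval of the reported value, 14 lay outside it in the same or an unresolved direction and 1 was reversed. Of the counts of 2-fold genes 195 stayed within 1.5 times the reported count and 83 did not. Of the type I interferon medians 123 stayed inside the central 95% of lists or on their side of it, 1 of them with the sign changed (NK cell-like, ambient profile subtracted), 15 moved outside it and 1 moved inside it. Of the other list medians 2632 stayed so, 206 of them with the sign changed, 184 moved outside, 30 of them with the sign changed, 135 moved inside with the sign kept and 33 left their side with the sign changed. Of the log2 ratios of named genes that reached 1.5-fold, 4063 stayed at 1.5-fold in the same direction, 458 were smaller with the same sign and 51 changed sign. Of those under 1.5-fold, 3207 kept and 176 changed their sign. The numbers of kept cells stayed within 1.5 times the reported ones under the 3 calling alternatives. No value was given for cDC2-like and regulatory T cell-like cells at a resolution of 0.5, for lists with fewer than 5 members, such as ketone body and neutrophil recruitment genes in other T cell-like cells, or for genes with 0 counts in both libraries. With the neutrophil rule the ketogenic library held 92 neutrophil-like cells, below the minimum of 100, so those values serve as a check only. Pseudocount and count minimums act through the number and shrinkage of genes at low counts; for the other values the cause was not tested. Below, each value is followed by the reported one in parentheses, and classes are given by short names.

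With genes centred within each library, the log2 share ratios were −1.17 (−1.32) for macrophages and −0.028 (0.11) for monocytes. Genes at 2-fold were then 5 (3) in CD8 T cells, 17 (26) in neutrophils and 6 (3) in other T cells among those higher, and 11 (5) in monocytes and 71 (35) in cDC2 among those lower. List medians stood at −0.14 (−0.084) in NK cells and −0.19 (−0.11) in neutrophils for type I interferon genes and −0.20 (0.28) in other T cells for inflammatory cytokine genes. Gene log2 ratios stood at Cxcl2 0.80 (−0.71) in CD8 T cells and Ccl2 −0.65 (0.99) in cDC2.

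With cells thinned before clustering, the log2 share ratios were −0.026 (0.11) for monocytes and 0.021 (−0.50) for neutrophils.

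With a mitochondrial limit of 20% and Scrublet's own thresholds, the log2 share ratios were 0.53 (0.76) for NK cells, −1.18 (−1.32) for macrophages, −0.042 (0.11) for monocytes, −0.15 (−0.50) for neutrophils and 1.41 (0.24) for plasmacytoid dendritic cells. The 2-fold genes numbered 9 (4) in monocytes, 12 (5) in macrophages, 16 (3) in CD8 T cells, 212 (26) in neutrophils, 13 (3) in other T cells and 38 (13) in cDC2 among those higher. The list medians were −0.048 (0.010) in macrophages for fatty acid genes, 0.092 (−0.33) in CD8 T cells for neutrophil recruitment genes, −0.35 (−0.11) in neutrophils for type I interferon genes, 1.15 (−1.16) in neutrophils for MHC class II genes, 0.41 (−0.49) in neutrophils for alternatively activated macrophage genes and 0.035 (−0.32) in neutrophils for hypoxia genes. The gene ratios were Prf1 0.064 (−0.59) and H2-Ab1 0.085 (−0.61) in monocytes, Cxcl2 1.80 (−0.71) in CD8 T cells, Slamf9 0.48 (−2.11), H1f0 0.46 (−1.62), Ecm1 0.33 (−1.54), Arg1 2.92 (−0.66), Iigp1 0.64 (−1.04), Irf8 0.46 (−0.68), H2-Aa 1.07 (−1.53), H2-Ab1 1.24 (−1.45), H2-DMb1 0.62 (−1.33), H2-Eb1 1.40 (−1.28), Pf4 0.26 (−2.57), Cxcl16 0.64 (−1.66), Ccl12 1.08 (−1.28) and Pcna 0.19 (−0.63) in neutrophils and Prf1 0.13 (−0.63) in other T cells.

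With mixed barcodes removed by a neutrophil rule as well, the log2 share ratio was −0.82 (−0.50) for neutrophils. Counts at 2-fold became 10 (26) in neutrophils and 5 (3) in other T cells among those higher, and 39 (78) in neutrophils and 85 (35) in cDC2 among those lower. Medians of lists became −0.15 (−0.084) in NK cells for type I interferon genes and −0.0043 (0.010) in macrophages and −0.11 (0.10) in neutrophils for fatty acid genes. Single genes stood at Retnla −1.40 (0.82) in macrophages, Cxcl2 1.38 (−0.71) in CD8 T cells, Gzmf −1.80 (2.58), Gem −0.65 (2.003), H1f0 0.97 (−1.62), Irf8 1.13 (−0.68), Il18bp 0.080 (−0.62) and Lipa 0.58 (−0.69) in neutrophils and Ccl2 −0.69 (0.99) in cDC2.

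With the highest 10% of Scrublet scores removed instead, the log2 share ratios were −1.18 (−1.32) for macrophages, 0.20 (0.61) for other T cells and 0.24 (0.44) for all T cells. There, 2-fold genes were 5 (3) in CD8 T cells and 6 (3) in other T cells among those higher, and 27 (13) in other T cells among those lower. Lists there had medians of −0.19 (−0.084) in NK cells and −0.15 (−0.11) in neutrophils for type I interferon genes, −0.024 (0.010) in macrophages for fatty acid genes, −0.027 (0.097) in macrophages for hypoxia genes, −0.051 (0.18) in CD8 T cells for cholesterol synthesis genes, −0.053 (0.28) in other T cells for inflammatory cytokine genes and −0.086 (0.46) in cDC2 for cytotoxic genes. Log2 ratios of genes were Prf1 0.30 (−0.59) in monocytes, Cd9 −0.20 (0.96), Hspa1a 0.10 (−1.13) and Prf1 0.036 (−0.63) in other T cells and Gzmc −0.97 (3.78) and Ccl2 −0.039 (0.99) in cDC2.

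Under the naming rule as first written, the log2 share ratio was 0.60 (0.11) for monocytes. Genes at 2-fold were then 10 (5) in monocytes among those lower. List medians stood at −0.085 (−0.38) in monocytes and −0.14 (−0.084) in NK cells for type I interferon genes. Gene log2 ratios stood at Ifit3b 0.30 (−0.86), Prf1 0.59 (−0.59) and Acod1 0.062 (−0.65) in monocytes and Ccl1 0.38 (−1.16) in NK cells.

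Clustered without the genes of both interferon lists, the log2 share ratio was −1.48 (−1.32) for macrophages. The 2-fold genes numbered 9 (3) in other T cells among those higher. The list medians were −0.10 (−0.084) in NK cells and −0.14 (−0.11) in neutrophils for type I interferon genes, −0.0093 (0.010) in macrophages for fatty acid genes and −0.021 (0.097) in macrophages for hypoxia genes. The gene ratios were Hspa1b −0.67 (0.85) in macrophages and Prf1 0.045 (−0.63) in other T cells.

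At a minimum of 1000 UMIs and 500 genes without the ambient test, the 2-fold genes numbered 9 (3) in other T cells and 31 (13) in cDC2 among those higher. Medians of lists became −0.15 (−0.11) in neutrophils for type I interferon genes. Single genes stood at Prf1 0.27 (−0.63) in other T cells.

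At a minimum of 250 UMIs and 150 genes, the 2-fold genes numbered 5 (3) in CD8 T cells and 8 (3) in other T cells among those higher, and 6 (13) in other T cells among those lower. Lists there had medians of −0.12 (−0.084) in NK cells and −0.14 (−0.11) in neutrophils for type I interferon genes and −0.14 (0.28) in other T cells for inflammatory cytokine genes.

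At a mitochondrial limit of 20%, the 2-fold genes numbered 6 (3) in CD8 T cells and 8 (13) in cDC2 among those higher. List medians stood at −0.088 (−0.084) in NK cells for type I interferon genes, 0.17 (−0.33) in CD8 T cells for neutrophil recruitment genes and −0.26 (0.28) in other T cells for inflammatory cytokine genes. Log2 ratios of genes were Cxcl2 2.07 (−0.71) in CD8 T cells, Prf1 0.039 (−0.63) in other T cells and Ccl2 −0.21 (0.99) in cDC2.

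With doublets and mixed barcodes kept, the 2-fold genes numbered 5 (3) in CD8 T cells, 6 (3) in other T cells and 5 (13) in cDC2 among those higher, and 10 (5) in monocytes, 6 (11) in macrophages and 6 (13) in other T cells among those lower. The list medians were −0.058 (0.17) in monocytes for regulatory T cell genes, −0.024 (0.010) in macrophages and −0.0035 (0.10) in neutrophils for fatty acid genes, 0.0053 (−0.33) in CD8 T cells for neutrophil recruitment genes, −0.17 (−0.11) in neutrophils for type I interferon genes and −0.067 (0.46) in cDC2 for cytotoxic genes. Gene log2 ratios stood at Cxcl2 1.08 (−0.71) in CD8 T cells and Gzmb −0.17 (1.77) in cDC2.

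At a Leiden resolution of 0.5, the 2-fold genes numbered 5 (3) in other T cells among those higher, and 10 (5) in monocytes among those lower. Medians of lists became −0.50 (0.28) in other T cells for inflammatory cytokine genes.

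At a Leiden resolution of 2, the 2-fold genes numbered 8 (4) in monocytes, 9 (3) in CD8 T cells and 17 (26) in neutrophils among those higher, and 9 (5) in monocytes and 6 (10) in NK cells among those lower. Lists there had medians of −0.11 (0.28) in other T cells for inflammatory cytokine genes. The gene ratios were Cxcl2 2.08 (−0.71) in CD8 T cells.

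With mixed barcodes removed by 4 lineage modules only, the 2-fold genes numbered 7 (4) in monocytes and 13 (3) in other T cells among those higher, and 53 (35) in cDC2 among those lower. List medians stood at −0.18 (−0.11) in neutrophils for type I interferon genes and −0.016 (0.46) in cDC2 for cytotoxic genes. Single genes stood at Gzmc −0.75 (3.78) and Ccl2 −0.56 (0.99) in cDC2.

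In CPM without mitochondrial and ribosomal protein genes, the 2-fold genes numbered 8 (3) in CD8 T cells and 7 (3) in other T cells among those higher.

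With the median of genes with at least 200 counts set to 0, the 2-fold genes numbered 10 (4) in monocytes and 8 (5) in macrophages among those higher, and 3 (5) in monocytes and 4 (11) in macrophages among those lower.

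After subtraction of the ambient profile, the 2-fold genes numbered 5 (3) in other T cells among those higher, and 9 (5) in monocytes among those lower. The list medians were 0.049 (−0.35) in NK cells for MHC class II genes, −0.029 (0.083) in NK cells for regulatory T cell genes, 0.50 (−0.25) in NK cells for chemokine genes and −0.0091 (0.010) in macrophages for fatty acid genes. Log2 ratios of genes were Lgmn 0.088 (−0.66) in NK cells.

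With each cluster given the same weight, the 2-fold genes numbered 1 (2) in NK cells among those higher. Medians of lists became −0.0053 (0.097) in macrophages for hypoxia genes.

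At a pseudocount of 1 CPM, the 2-fold genes numbered 16 (4) in monocytes, 9 (2) in NK cells, 21 (5) in macrophages, 25 (3) in CD8 T cells, 12 (3) in other T cells and 27 (13) in cDC2 among those higher, and 81 (5) in monocytes, 44 (10) in NK cells, 127 (11) in macrophages, 45 (14) in CD8 T cells, 119 (78) in neutrophils and 88 (35) in cDC2 among those lower.

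With genes of at least 200 counts, the 2-fold genes numbered 1 (2) in NK cells, 1 (3) in CD8 T cells, 10 (26) in neutrophils, 0 (3) in other T cells and 2 (13) in cDC2 among those higher, and 3 (5) in monocytes, 7 (11) in macrophages, 6 (14) in CD8 T cells, 23 (78) in neutrophils, 2 (13) in other T cells and 4 (35) in cDC2 among those lower.

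With genes of at least 1 count, the 2-fold genes numbered 7 (3) in CD8 T cells, 54 (26) in neutrophils, 69 (3) in other T cells and 45 (13) in cDC2 among those higher, and 22 (14) in CD8 T cells, 195 (78) in neutrophils, 108 (13) in other T cells and 133 (35) in cDC2 among those lower.

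With list members of at least 100 counts, the list medians were 0.49 (−0.25) in NK cells for chemokine genes and −0.017 (0.010) in macrophages for fatty acid genes.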

Other observations

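The fibroblast-like cluster was led by Rhox5 and Dcn, with Rhox5 a reproductive homeobox gene and Dcn a matrix proteoglycan, and held cells of very high depth, with a median of 36397 UMIs. Xist, the RNA of the inactive X chromosome in female cells, was at 8.74 CPM in the normal and 7.39 CPM in the ketogenic library in this cluster, against 619 and 445 CPM over all called barcodes. The mice were female per the labels, so the low Xist in both libraries argues against host fibroblasts as most of these cells. Whether they are tumor cells, or tumor cells with some host fibroblasts, was not tested. Their depth would also fit more than 1 cell per barcode, which was not tested either.

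Several noncoding RNAs stood apart in all classes together, and they were chosen after their values were seen. Over all called barcodes Neat1, the scaffold of nuclear paraspeckles, was at 354 CPM in the normal and 162 CPM in the ketogenic library and Gm42418, which overlaps a ribosomal RNA repeat, at 4180 and 2181 CPM, while Malat1, a nuclear speckle RNA, was at 12087 and 11729 CPM. Mast cell or basophil-like cells had the most Neat1, 3521 and 2579 CPM.

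Hemoglobin transcripts in NK cell-like cells came mostly from 1 cell. In the normal library 1779 of 1959 hemoglobin UMIs of this class (90.8%) lay in a single barcode, against 25 hemoglobin UMIs over the 1584 NK cell-like cells of the ketogenic library. In CD8 T cell-like cells of the normal library 42 of 47 hemoglobin UMIs (89.4%) lay in 1 cell. The values were chosen after they were seen.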
